A study of Mus with 6 samples.

How the data were processed

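Small RNA libraries of mouse adipocytes were analysed from the deposited tables, 1 table for each of 3 control and 3 CIH libraries. Total RNA had been extracted with a miRNA isolation kit and column purification and sequenced on an Illumina instrument, per the labels. The submitters' processing notes name featureCounts 1.5.0-p3, DESeq 1.8.3 and the GRCm38 genome build, with no role or order for each. The adapter trimming, the aligner, the miRBase release and the rule for reads that match several miRNAs are not given in the sources used here.

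The deposited values are whole-number counts of reads per mature miRNA, without normalization. In 3 of the 6 tables the header names the column FPKM, but all values there are whole numbers that sum to a different total in each library, so they were taken as counts. The tables hold 2 different lists of names. The 4 libraries numbered 1 and 2 share a list of 1053 names, of which 1024 are known miRNAs and 29 are predicted ones. The 2 libraries numbered 3 share a list of 1186 names, of which 1116 are known and 70 predicted. The 929 known names in both lists entered the tests and hold 99.97% or more of each library. Predicted names were left out of the tests because their numbering need not match between the lists, and 0 columns of other samples were present.

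Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust, TMM normalization, filterByExpr with its defaults) in R 4.3.3, with group as the only term, all 6 libraries in the fit and Benjamini-Hochberg adjustment at 0.05. Lists of miRNAs were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with the estimated correlation and fry beside it, where at least 3 members were tested. Of 26 lists fixed beforehand, 8 of them for other cell types that adipocyte preparations can hold, 23 had enough members for a test. Measures of library composition were compared with a two-sided exact permutation test. DESeq2 1.42.0 and limma-voom served as alternative tests. Tables were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. CPM values are counts divided by the total of the whole library and scaled to the same total in each.

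The groups, tests, lists, alternatives and the rule for naming miRNAs were set before the data were examined. The rule named, in each direction, the 10 miRNAs with the largest log2 difference among those called with a mean of at least 10 CPM and ranges that did not overlap. Where none was called, it named the 8 with the smallest p in each direction as values that did not pass. It also named up to 3 miRNAs of each list by smallest p, the 5 most abundant miRNAs and both arms of miR-210. In the libraries numbered 1 and 2 the same rule was passed by 12 miRNAs that rose and 19 that fell. Members called in a list there and members of the X-linked groups were named in addition, after their values were seen.

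The alternatives set beforehand were other scalings, other tests, other filters on low counts, a threshold of 0.1, the replicate number as a block, leaving out the 10 most abundant miRNAs and leaving out each library in turn. Added after the data were examined were the fit of the libraries numbered 1 and 2 alone, the set as a term in the model, sample weights with that term, and the interaction of group and set, whose spread comes from the libraries numbered 1 and 2 alone. The log2 difference in the pair numbered 3 was computed after TMM scaling with 0.5 CPM added. The TMM factors were 0.636 for control library 3 and 1.11 for CIH library 3. This scaling lowers the log2 differences of that pair, so signs near 0 there depend on it.

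Whether equal library numbers pair the libraries was checked by correlating deviations from the group means across miRNAs. Libraries of the same number correlated at 0.31, 0.35 and 0.40, each over 0.1, so the numbers were treated as pairs in the blocked fit. Control library 1 correlated as closely with CIH library 2 (0.40), and within the libraries numbered 1 and 2 the same-number correlation was 0.071. Libraries of one group differed by more than counting noise in every pair (chi-square per degree of freedom of 135 or more), as separate preparations of the same RNA would too, so this does not show separate replicates. Each deposited library was counted as 1 replicate by its label. Nothing in the labels says that the libraries came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

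Total counts ran from 6291101 to 11264151. Reads carry no molecular identifiers in the sources used here, so floors and intervals cover counting error only. The fits were tested on simulated counts with 200 changed miRNAs. With the spread of the libraries numbered 1 and 2, 56% of 2-fold and 92% of 4-fold changes were recovered among 459 miRNAs, with 8 calls among 259 unchanged ones. Positions come from a RefSeq table of GRCm38.p6, in which 891 of the 929 names were matched, and give the span of each precursor gene without its strand. Among names with a mean of at least 5 counts, there were 9 pairs whose counts agreed within 2% in every library. These include miR-338-3p and miR-3065-5p, miR-24-3p and miR-3074-5p, and miR-1a-3p and miR-1b-5p, and the values of all 9 pairs are uncertain.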

Results

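Small RNA was sequenced from mouse adipocytes of wild-type C57BL/6 background. The labels give 3 control libraries and 3 libraries of a model group exposed to chronic intermittent hypoxia (CIH), a regime of repeated falls in oxygen used to model sleep apnoea. The comparison asks which mature miRNAs differ between exposed and control adipocytes. Total counts were 6291101, 9720485 and 8259937 in control libraries 1, 2 and 3, and 7336758, 10042644 and 11264151 in CIH libraries 1, 2 and 3. A count of 3, taken as the floor, corresponds to 0.266 to 0.477 CPM (counts scaled to a common library total) at these depths, and this floor covers counting error only. The names below are mature miRNAs of the mouse, written without the species prefix. Positions are those of the precursor genes on GRCm38.

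A few miRNAs made up most of each library, and which one led depended on the library number. miR-21a-5p, from a precursor on chromosome 11 (86584067 to 86584158) within the span of Vmp1, took 37.4% and 37.6% of control libraries 1 and 2 and 43.2% and 51.6% of CIH libraries 1 and 2. In the libraries numbered 3, miR-148a-3p led instead, with 49.4% of the control and 24.9% of the CIH library, against 2.81% to 5.53% in the other 4 libraries. miR-143-3p, miR-146b-5p and miR-10b-5p completed the 5 most abundant miRNAs. The 10 most abundant names together took 81.2% ± 4.78 of the control and 80.5% ± 2.21 of the CIH libraries (SD, n = 3 each; two-sided exact permutation p = 0.9).

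**Figure D1:**
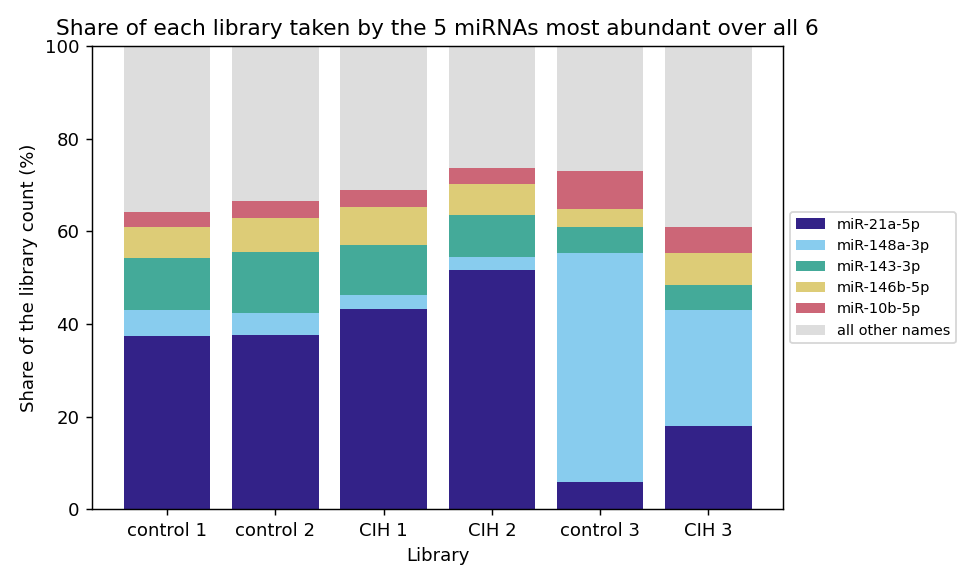
Share of the library count in percent (vertical axis) taken by the 5 most abundant miRNAs in each of the 6 libraries (horizontal axis), with all other names in grey. miR-21a-5p leads in the 4 libraries numbered 1 and 2 (37.4% to 51.6%), and miR-148a-3p leads in both libraries numbered 3 (49.4% and 24.9%).

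The libraries numbered 3 stood apart from the rest in both groups. Across 650 miRNAs, which are not independent replicates, log CPM correlated at r = 0.987 to 0.996 among the 4 libraries numbered 1 and 2. Between these and the libraries numbered 3 the range was 0.943 to 0.958. The pair numbered 3 correlated at 0.947, so its 2 libraries were no closer to each other than to the rest. The files of the libraries numbered 3 also list a different set of names. With group in the model, 114 of 456 miRNAs differed between these sets (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 52 higher and 62 lower in the libraries numbered 3. The pooled values below therefore stand beside those within the libraries numbered 1 and 2 and the difference in the pair numbered 3, which has 1 library per group and so no spread of its own.

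In the comparison of all 6 libraries, miR-221-3p and miR-222-3p, neighbours on chromosome X that are known regulators of the cell cycle inhibitor p27, had higher levels in every CIH library than in any control. miR-222-3p stood at 505 ± 93.2 CPM in CIH and 190 ± 85.2 CPM in control (SD, n = 3 each), a log2 difference of 1.33 (SE 0.39). miR-221-3p stood at 1346 ± 202 against 489 ± 329 CPM, a log2 difference of 1.49 (SE 0.55). On the lower side, miR-193b-3p, reported to favour brown adipocyte differentiation, stood at 17.2 ± 1.25 CPM in CIH and 39.9 ± 13.0 CPM in control, a log2 difference of -1.34 (SE 0.42). miR-30a-5p, reported to favour adipocyte differentiation, stood at 10210 ± 2804 against 27980 ± 10640 CPM (log2 difference -1.78, SE 0.66), with -0.79 (adjusted p = 0.0939) within the libraries numbered 1 and 2 and -3.12 in the pair numbered 3. None of these passed the adjustment.

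edgeR's quasi-likelihood test called 0 of 456 miRNAs, with 23 at an unadjusted p under 0.05 and a smallest adjusted p of 0.834. DESeq2 and limma-voom also called 0, with 37 and 21 at an unadjusted p under 0.05. The CPM ranges of the 2 groups did not overlap for 51 miRNAs (11.2%), where chance gives 10%. On simulated counts with the spread of these 6 libraries, the same test recovered 0% of 2-fold and 2% of 4-fold changes among 456 miRNAs.

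Of the 8 miRNAs with the smallest p-values on the higher side, miR-344d-3p stood at 123 ± 53.9 CPM in CIH and 32.5 ± 17.4 CPM in control (log2 difference 1.86, SE 0.51), and its within-set values were 1.33 and 2.93. miR-690 stood at 14.9 ± 2.36 against 5.57 ± 1.83 CPM, with log2 differences of 1.25 within the libraries numbered 1 and 2 and 1.28 in the pair numbered 3. miR-344d-3-5p, miR-7649-5p and miR-187-3p had means below 10 CPM in both groups. miR-146a-5p, a known target of NF-kB, owed its log2 difference of 4.16 (SE 1.57) to CIH library 3, at 1964 CPM against 24.3 to 45.5 CPM in the other 5 libraries. Without that library its log2 difference was 0.18. Within the libraries numbered 1 and 2 it was 0.88 (SE 0.31, adjusted p = 0.0705), at 45.5 and 37.2 CPM in CIH and 24.3 and 24.9 CPM in control.

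On the lower side, miR-148a-5p stood at 224 ± 10.7 CPM in CIH and 561 ± 221.9 CPM in control (log2 difference -1.68, SE 0.59). Its within-set values were -0.82 (SE 0.22) in the libraries numbered 1 and 2 and -2.63 in the pair numbered 3. The pooled -1.86 of miR-30c-2-3p rested on the pair numbered 3, at -3.56, against -0.20 (adjusted p = 0.740) in the libraries numbered 1 and 2. The pooled -1.35 of miR-335-3p rested on the libraries numbered 1 and 2, at -2.11 against 0.00356 in the pair numbered 3. Before TMM scaling that pair held 11.3 CPM in control and 19.7 CPM in CIH. The others were miR-293-3p, at -2.83 (within-set -2.17 and -3.23), and miR-338-3p and miR-3065-5p, both at -2.35 (within-set -2.17 and -1.66). In CIH library 3 miR-293-3p stood at 0 CPM and the other 2 at 0.0888 CPM, below the floor of 0.266 CPM (3 counts), so their values in the pair numbered 3 depend on the 0.5 CPM added. miR-338-3p and miR-3065-5p come from precursors at overlapping positions on chromosome 11 and hold identical counts in every library, so the reads behind them cannot be assigned to one name.

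**Figure D2:**
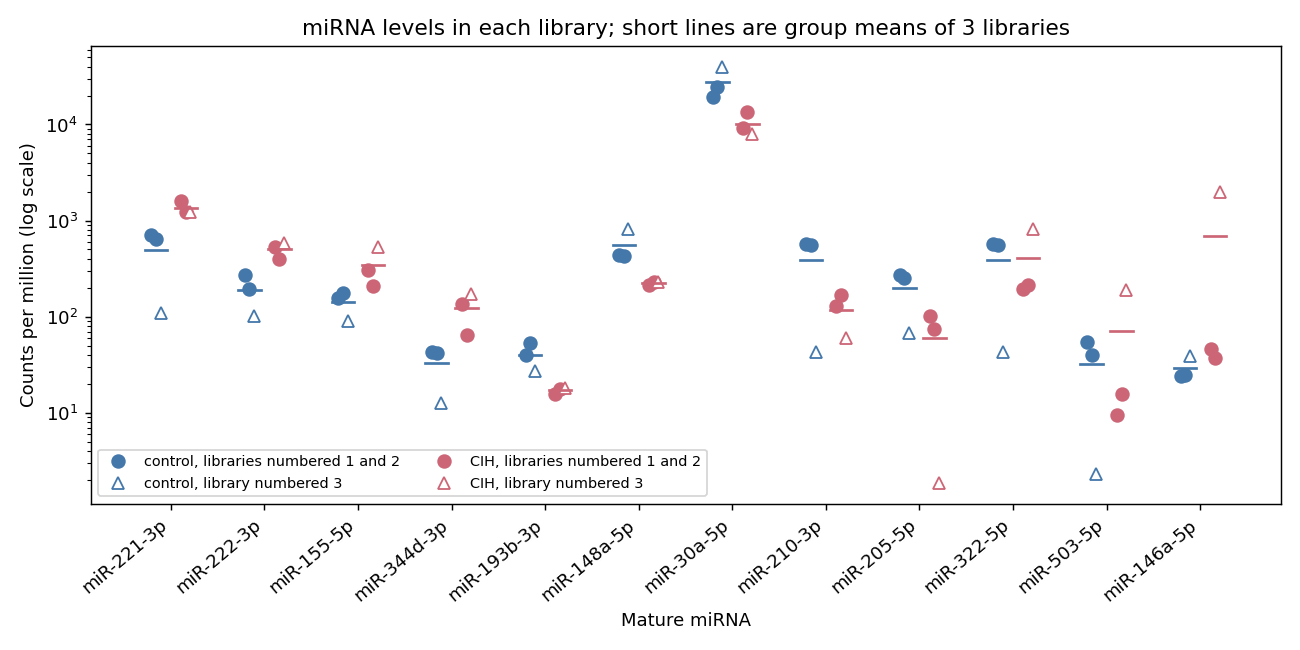
CPM on a log axis (vertical) for 12 miRNAs (horizontal) in each library, with control in blue and CIH in red; filled circles are the libraries numbered 1 and 2, open triangles the libraries numbered 3, and short lines the group means of 3 libraries. miR-222-3p lies at 401 to 580 CPM in CIH and 102 to 272 CPM in control, and miR-146a-5p is high in CIH library 3 alone (1964 CPM).

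Among the lists of miRNAs chosen beforehand, 7 of 23 tested differed between CIH and control in the 6 libraries (camera with a preset correlation of 0.01, Benjamini-Hochberg over the lists). None of the 7 held with an estimated correlation (adjusted p = 0.554 for 6 lists and 0.571 for the hypoxia-induced list), and fry called 0 lists. For the brown and beige fat list the estimate (0.0102) was close to the preset, yet camera's unadjusted p went from 0.00575 to 0.0503. The loss for that list therefore does not show correlation among its members. The cluster of miR-221 and miR-222 was higher, with 4 of 4 members higher, a median log2 difference of 1.16 and an adjusted p of 0.000727. It counted 0 calls over all miRNAs and 1 adjusted over the list alone. The inflammation list was higher (13 of 16 members, median 0.60, adjusted p = 0.0193), with miR-155-5p at 347 ± 162 CPM in CIH and 140 ± 44.5 CPM in control and miR-187-3p at 5.30 ± 2.08 against 1.67 ± 0.49 CPM. The anti-adipogenic list was higher (21 of 28, median 0.21, adjusted p = 0.00828), as were the miR-23/27/24 clusters (8 of 9, median 0.49, adjusted p = 0.0309) and the hypoxia-induced list (22 of 29, median 0.43, adjusted p = 0.0407). The brown and beige fat list was lower (15 of 24, median -0.21, adjusted p = 0.0309), and so was the cluster of miR-183, miR-96 and miR-182 (4 of 5, median -0.69, adjusted p = 0.0357). In these 6 lists 0 members were called, over all miRNAs or adjusted over the list alone. The 7 lists share members, so they are not separate results. Both arms of miR-155 are in the hypoxia-induced, anti-adipogenic and inflammation lists. miR-221-3p is in the anti-adipogenic and inflammation lists and in its own cluster. miR-182-5p is in the brown and beige fat list and in the cluster of miR-183, miR-96 and miR-182.

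Without control library 3 the count of lists was 3, and without CIH library 3 it was 2, while without control library 2 it was 12. With the replicate number as a block, the miR-181 family was also called higher (adjusted p = 0.0464) and the epithelial list lower (adjusted p = 0.0380). Both calls used camera with the preset correlation. Without the block, camera with an estimated correlation gave both lists an adjusted p of 0.571. Of 12 settings with the preset correlation, the cluster of miR-221 and miR-222 was called in all 12, the inflammation list in 10, and the anti-adipogenic list, the brown and beige fat list and the cluster of miR-183, miR-96 and miR-182 in 9 each. The hypoxia-induced list and the miR-23/27/24 clusters were called in 7 each. The settings that lost the lists called in 9 were the 3 that leave out a library numbered 3, and within the libraries numbered 1 and 2 the adjusted p was 0.281 for the anti-adipogenic list and 0.638 for the other 2.

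The other 16 tested lists did not pass in the 6 libraries. They were the pro-adipogenic (adjusted p = 0.225) and p53-linked lists (0.693), the let-7 (0.662), miR-29 (0.0844), miR-30 (0.314), miR-15/16 (0.382) and miR-181 (0.0928) families, and the miR-17-92 (0.559), miR-143 and miR-145 (0.985), Dlk1-Dio3 (0.285) and Sfmbt2 (0.261) lists. The remaining ones mark other cell types: erythroid cells (0.225), muscle (0.169), epithelium (0.0688), neurons (0.113) and fibroblasts and stroma (0.679). For the pro-adipogenic list the median was 0.02, the mean -0.19 and the test downward, and for the let-7 family 0.01, 0.05 and downward. The lists of leukocytes, endothelium and hepatocytes had under 3 tested members and no test.

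Among the markers of other cell types, the summed epithelial miRNAs were lower in CIH in each numbered pair. In the pair numbered 3 this rested on miR-205-5p, at 67.8 CPM in control and 1.86 CPM in CIH. There miR-203-3p stood at 6.66 CPM in control and 7.55 CPM in CIH, so the sum does not show that all members moved together. The summed epithelial level was 424, 350 and 79.9 CPM in control libraries 1, 2 and 3 and 176, 129 and 19.4 CPM in CIH libraries 1, 2 and 3 (two-sided exact permutation p = 0.3, adjusted p = 0.99 over 11 measures of composition). Summed muscle miRNAs ranged from 27.5 to 206 CPM in control and from 24.9 to 76.7 CPM in CIH, but miR-1a-3p and miR-1b-5p hold nearly the same counts, and with these taken once the ranges were 15.8 to 114 and 14.3 to 41.2 CPM. Erythroid miRNAs ranged from 93.9 to 203 and from 56.1 to 195 CPM, with close levels of miR-486a-5p and miR-486b-3p (46.5 and 44.2 CPM in control library 3) that can stem from shared reads. The hepatocyte miRNA ranged from 2.16 to 4.12 and from 2.09 to 5.59 CPM. Leukocyte miRNAs stood at 12.0 ± 0.64 CPM in control and 15.1 ± 7.25 CPM in CIH (SD, n = 3 each), endothelial at 87.8 ± 51.7 and 92.4 ± 16.8 CPM and neuronal at 371 ± 172 and 389 ± 174 CPM. Fibroblast and stromal miRNAs stood at 118800 ± 45130 and 120700 ± 14070 CPM, but these close means hide a difference between the sets. Their sum was 135900 and 152900 CPM in control libraries 1 and 2 and 123200 and 105600 CPM in CIH libraries 1 and 2. In the pair numbered 3 it was 67610 CPM in control and 133500 CPM in CIH, with miR-199a-3p at 3220 and 42470 CPM. miR-143-3p alone stood at 101600 ± 39760 and 84690 ± 27040 CPM, so a sum of this size does not measure stromal cells. With 3 libraries against 3, the smallest two-sided p this exact test allows is 0.1.

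Within the 4 libraries numbered 1 and 2, a comparison added after the data were examined, 19 miRNAs rose and 24 fell among 459 tested (edgeR quasi-likelihood test, adjusted p under 0.05, 2 libraries per group). miR-221-3p rose by 1.18 on the log2 scale (SE 0.21, adjusted p = 0.000216) and miR-222-3p by 1.14 (SE 0.22, adjusted p = 0.000723). miR-344d-3p rose by 1.33 (SE 0.30), miR-218-5p by 0.83 (SE 0.22) and miR-92a-3p by 1.13 (SE 0.22). Both arms of miR-155 rose, miR-155-5p by 0.76 (SE 0.23) and miR-155-3p by 1.69 (SE 0.41). miR-219a-1-3p, miR-1198-5p, miR-690, miR-1964-3p and miR-139-5p also rose, by 1.57, 1.56, 1.25, 1.22 and 1.10.

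Those that fell included both arms of miR-210, both arms of miR-148a and several X-linked miRNAs. miR-210-3p, the usual target of the hypoxia-inducible factor HIF-1, stood at 565 and 551 CPM in control libraries 1 and 2 and at 129 and 167 CPM in CIH libraries 1 and 2. The log2 difference was -1.75 (SE 0.24, adjusted p = 1.9e-05), and that of miR-210-5p was -2.44 (SE 0.42, adjusted p = 0.000215). miR-335-3p, whose precursor lies within the span of Mest on chromosome 6, fell by 2.11 (SE 0.33). miR-503-5p, miR-450b-5p, miR-322-5p and miR-542-3p fell by 1.73, 1.64, 1.30 and 1.20, and their precursors lie on chromosome X between 53047997 (the start of Mir450b) and 53054349 (the end of Mir322). miR-205-5p fell by 1.44 (SE 0.24), miR-193b-3p by 1.32 (SE 0.33), miR-203-3p by 1.25 (SE 0.31) and miR-743b-3p by 1.18 (SE 0.32). miR-148a-5p and miR-148a-3p fell by 0.82 (SE 0.22) and 0.66 (SE 0.21).

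With total counts alone as the scaling, 7 rose and 27 fell in this set, with 31 of the 43 still called, and the median of all tested miRNAs moved from -0.03 to -0.17 on the log2 scale. The count of 43 was 14 without control library 1, 9 without control library 2, 23 without CIH library 1 and 97 without CIH library 2. The single library left in a group is then assumed to vary like the other group.

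The pair numbered 3 did not follow the same directions for many of these miRNAs. Of the 43, 25 (58.1%, exact 95% interval 42.1% to 73.0%, with miRNAs treated as independent) differed in the same direction there, 11 of the 19 that rose and 14 of the 24 that fell. Over all 447 miRNAs with a value in both sets the share was 50.8% (Spearman rho 0.0468 across miRNAs, which are not independent). miR-221-3p and miR-222-3p were higher by 2.68 and 1.70 in that pair and miR-193b-3p was lower, at -1.35. miR-503-5p and miR-322-5p were higher there, by 5.36 and 3.44, and miR-92a-3p was lower, at -2.02. For miR-210-3p the pair held 43.0 CPM in control and 59.6 CPM in CIH, which is a log2 difference of -0.33 after TMM scaling, so its direction there depends on the scaling. Over all 6 libraries its log2 difference was -1.60 (SE 0.80, adjusted p = 0.885), and that of miR-210-5p was -2.09 (SE 0.93, adjusted p = 0.838). In the pair numbered 3 miR-210-5p was higher in CIH, at 1.86 against 0.605 CPM (log2 difference 0.59).

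**Figure D3:**
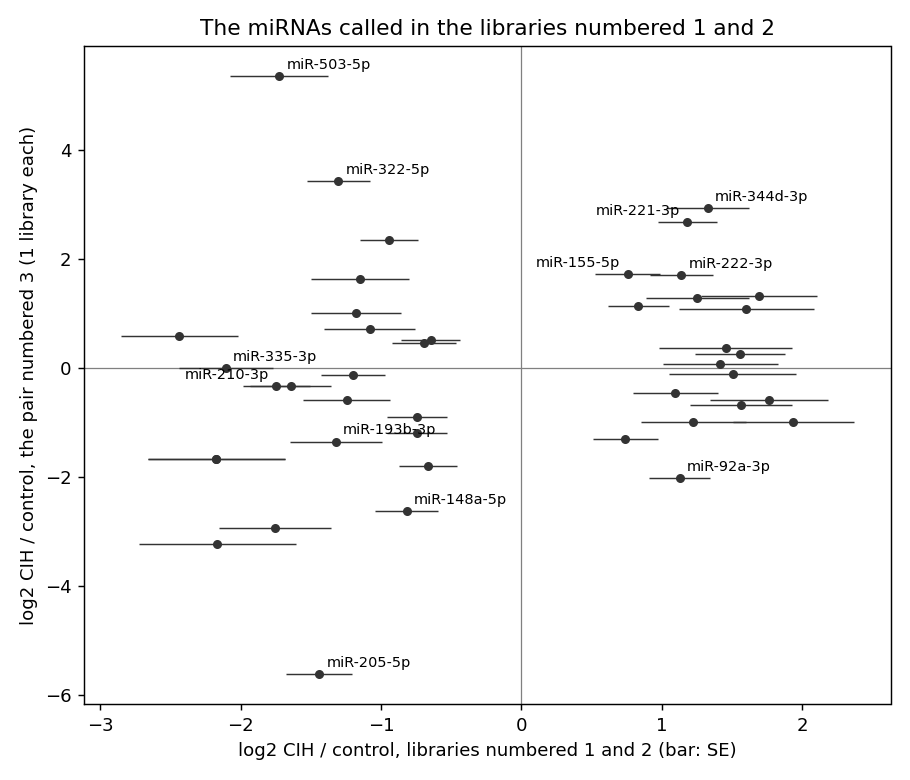
Log2 ratio of CIH to control in the libraries numbered 1 and 2 (horizontal axis, bars show the SE) against that in the pair numbered 3 (vertical axis, 1 library per group) for the 43 miRNAs called in the libraries numbered 1 and 2. Points in the upper right and lower left share a direction (25 of 43), and miR-503-5p and miR-322-5p lie in the upper left, at 5.36 and 3.44 in the pair numbered 3.

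An interaction of group and set, chosen after these directions were seen, was called for 138 of 456 miRNAs, 27 of them among the 43. The fit assumes that the single libraries of the pair numbered 3 vary like the libraries numbered 1 and 2, so it counts any difference between these 2 libraries and does not show that the effect of CIH differs. The 43 were chosen by their values in the libraries numbered 1 and 2, which by itself favours a difference.

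Of the lists, 6 differed within the libraries numbered 1 and 2. The inflammation list was higher (14 of 16 members, 4 rose and 0 fell, 6 adjusted over the list alone, adjusted p = 0.00119), with miR-155-5p, miR-155-3p, miR-187-3p and miR-221-3p as the members that rose. The cluster of miR-221 and miR-222 was higher (4 of 4, 2 rose, 3 adjusted over the list alone, adjusted p = 0.00119), as were the miR-17-92 group (12 of 16, 2 rose, 4 adjusted over the list alone) and the list named for the Sfmbt2 cluster (19 of 23, 0 rose, 0 adjusted over the list alone), each with an adjusted p of 0.0385. The latter goes by name, takes in miRNAs elsewhere such as miR-466i-5p on chromosome 13, and counts names with identical counts (miR-467a-5p and miR-467b-5p) separately. The 20 names that lie side by side on chromosome 2 (17 higher) did not pass (adjusted p = 0.1485 over 28 groups of neighbours). The epithelial list was lower (7 of 7, 3 fell, 3 adjusted over the list alone, adjusted p = 0.00990), with miR-205-5p, miR-205-3p and miR-203-3p as the members that fell. Stromal miRNAs were lower in 13 of 13 (0 fell, 2 adjusted over the list alone, adjusted p = 0.0270). With an estimated correlation none of the 6 held (adjusted p = 0.666 to 0.813), and fry called the inflammation list alone (adjusted p = 0.0162). The estimate was below the preset for the inflammation (-0.027), miR-221 and miR-222 (-0.215) and Sfmbt2 lists (-0.021). Even so, camera's unadjusted p went from 5.4e-05 to 0.0487 for the inflammation list, so correlation among members does not explain that loss. For the miR-17-92, epithelial and stromal lists the estimate was above the preset (0.106, 0.147 and 0.227).

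In the same 4 libraries the hypoxia-induced list did not pass (16 of 29 higher, median 0.09, mean -0.02, adjusted p = 0.882, 7 adjusted over the list alone). Of its members, miR-155-5p and miR-155-3p rose, while both arms of miR-210 and of miR-322 fell. The anti-adipogenic list had 4 members that rose and 0 that fell (miR-155-5p, miR-155-3p, miR-221-3p and miR-222-3p) among 29, with a median of -0.02 against a mean of 0.14 and an adjusted p of 0.281. The pro-adipogenic list had 2 that fell, both arms of miR-148a, among 32.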

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

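The predicted miRNA named novel_51, left out of the tests, had a higher level in both CIH libraries that list it, at 70.6 and 61.6 CPM (mean 66.1 CPM), than in both controls, at 51.7 and 43.5 CPM. It was singled out because, among names outside the tests, its CIH libraries all lay above its controls. With 2 libraries against 2, chance alone often gives that order. It is listed under this name in the libraries numbered 1 and 2 alone. The difference was not tested because predicted names were left out of the tests.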

How the results depend on the processing

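Over all 6 libraries the count of called miRNAs was 0 under every alternative set beforehand, from DESeq2 to leaving out each library in turn. With the replicate block it was 0 as well. At the preset correlation the block called 9 lists in place of 7, adding the miR-181 family and the epithelial list and changing no other call. Without the block, camera with an estimated correlation gave these 2 lists an adjusted p of 0.571 each. Of the alternatives added after the data were examined, the set as a term and sample weights called 0, and the libraries numbered 1 and 2 alone called 43. Scaling moved the median log2 difference of all tested miRNAs from 0.04 to -0.06 (RLE), -0.08 (upper quartile) and 0.15 (total counts).

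The count of 7 lists was 0 with an estimated correlation and 0 with fry, and 2 to 12 with each library left out in turn. Within the libraries numbered 1 and 2 the count of 43 ranged from 9 to 97 with each library left out, was 23 with at least 10 CPM in 3 libraries, where 246 miRNAs were tested in place of 459, and 65 at an adjusted p under 0.1, a laxer threshold. The stricter filter shared all 23 with the 43, DESeq2 34 of its 35 and limma-voom 33 of its 35. The replicate block called 48 there, 42 of them shared.

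Signs of miRNAs that were not called in the 6 libraries turned in some settings, and apart from the libraries left out the cause was not tested. miR-503-5p was at 1.18 over all libraries, and at -0.19 with the replicate block, -1.19 without CIH library 3, -1.73 in the libraries numbered 1 and 2, -0.18 with the set as a term and -1.20 with sample weights. miR-322-5p was at 0.12, and at -0.015 with upper quartile scaling, -0.0305 with the replicate block, -0.34 without control library 3, -0.79 without CIH library 3, -1.30 in the libraries numbered 1 and 2, -0.0204 with the set as a term and -0.94 with sample weights. miR-10b-5p was at -0.69, and at 0.40 without control library 3, 0.14 in the libraries numbered 1 and 2 and 0.0166 with sample weights. With each library left out in turn, miR-503-5p ranged from -1.19 to 1.77, miR-322-5p from -0.79 to 0.55, miR-10b-5p from -0.98 to 0.40, miR-148a-3p from -3.41 (without CIH library 3) to 1.11 (without control library 3), and miR-92a-3p from -0.14 (without CIH library 1) to 0.74, with -0.0283 without control library 2. miR-22-3p, at 0.17 over all libraries, ranged from -0.36 (without control library 3) to 0.75 (without CIH library 3), with -0.17 without CIH library 1 and -0.25 without CIH library 2, and miR-214-3p, at 1.46, was at -0.23 in the libraries numbered 1 and 2. The pseudocount and the summing of repeated names were not run, since the tables hold counts and no name occurs more than once.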

Other observations

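The tests of the pair numbered 3 and of miR-146a-5p, the X-linked groups and the comparison of both sets of libraries were chosen after the results were seen. So were the readings of 2 tests: the share of directions in the pair numbered 3 was read with its exact interval, and the 3 splits of 4 libraries were read as too few to decide, although the bound written beforehand for them was met. The share of 58.1% also met its own bound of under 60%, and both readings moved the outcome from argued against to open.

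Of the 6 tested groups of neighbouring miRNAs on chromosome X, 3 passed within the libraries numbered 1 and 2 with the preset correlation and 0 with an estimated one. The estimated version also weakened lists whose estimate lay below the preset, so its 0 does not show correlation among neighbours. Of the 10 tested arms of miR-322, miR-351, miR-450b, miR-503 and miR-542, 9 were lower in CIH and 5 fell (median log2 difference -0.84, camera adjusted p = 5.7e-05 over 28 groups of neighbours at most 10000 bases apart, but adjusted p = 0.810 with an estimated correlation). In the pair numbered 3 only 2 of them were lower, miR-450b-5p (-0.33) and miR-542-3p (-0.12), and the median of the group was 2.51. Before TMM scaling both were higher in CIH there, at 76.2 against 55.0 CPM and 981 against 609 CPM. All 13 tested arms of a second group, which holds miR-741-3p, miR-743b-3p and miR-881-3p, were lower, and these 3 fell (median -0.77, adjusted p = 0.000289, and adjusted p = 0.827 with an estimated correlation). In the pair numbered 3 only 3 of the 13 arms were lower, the median of the 13 was 0.71, and miR-743b-3p was higher, at 1.01. The third called group, miR-221 and miR-222, was higher in 4 of 4 in both sets (medians 0.93 and 1.86, adjusted p = 0.810 with an estimated correlation).

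The stromal miRNAs miR-199a and miR-214, which have neighbouring precursors on chromosome 1, had other values in each set. Whether all their reads come from these precursors was not tested. Their 4 tested arms had a median of -0.22 in the libraries numbered 1 and 2 and 3.10 in the pair numbered 3, and their interactions of group and set ran from 2.67 (miR-199a-5p, SE 0.49) to 3.88 (miR-214-3p, SE 0.38), with the spread of the libraries numbered 1 and 2 assumed for the single libraries numbered 3. miR-22-3p averaged 19160 CPM in the libraries numbered 1 and 2 and 690 CPM in the libraries numbered 3 (log2 difference -4.42, SE 0.34), and miR-148a-3p 40060 and 371300 CPM (3.60, SE 0.31).

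That the libraries numbered 3 stand apart in both groups is the first pattern. A difference in depth is argued against, since 106 miRNAs differed between the sets after every library was thinned to the shallowest total, 98 of them among the 114 called before. A preparation or read processing that treats both arms of a precursor differently stays open: across 42 precursors the arms had a Spearman rho of 0.232 (permutation p = 0.138), between the bounds set for either outcome. These 42 were limited to arms with a log2 CPM of at least 4. Of those among them with both arms called, 4 (miR-10b, miR-148b, miR-28a and miR-30e) had arms that differed in opposite directions and 4 in the same. Precursors with a less abundant arm, such as miR-542, are not in this count. For the CIH effect in the libraries numbered 1 and 2 the rho between arms was 0.489. The list of the libraries numbered 3 holds 249 names at 0 counts in both of them. The list of the libraries numbered 1 and 2 holds 0 names without counts in all of them. Names without counts cannot come from the material of these libraries, which argues against material alone as the source of the different lists. All 3 headers that name FPKM belong to the libraries numbered 1 and 2. Whether the differing counts come from another run of the read processing or from other material stays open, since the labels name no batch.

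The second pattern is the set of 43 calls within the libraries numbered 1 and 2. A few miRNAs taking most of the counts is argued against for the fit with TMM scaling, since 44 were called without the 10 most abundant ones, 42 of them shared. TMM already limits the weight of extreme miRNAs, so leaving these out is a weak test. With total counts alone, which abundant miRNAs do affect, 34 were called, 31 of them shared, and all 43 kept their sign. The other 2 splits of these 4 libraries gave at most 0 calls, but 3 splits cannot give a share under 0.05. An effect of CIH shared by the libraries numbered 3 stays open, since 58.1% of the 43 had the same direction there against 50.8% of all 447 miRNAs, and the exact interval (42.1% to 73.0%) ends below the share set for a shared effect but rests on 1 pair and on miRNAs that are not independent. miR-221-3p and miR-222-3p were higher in all 3 CIH libraries than in every control, but ranges that do not overlap were found for 51 of 456 miRNAs (11.2%) where chance gives 10%, and over all 6 libraries neither passed (adjusted p = 0.834).

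The third pattern is the level of miR-146a-5p in CIH library 3, where it held 22126 counts. RNA of leukocytes is argued against, since miR-142a-3p and miR-223-3p had 0 counts there, 0% of the miR-146a-5p level, with a floor of 0.266 CPM. Another miRNA of the leukocyte list, miR-342-3p, was highest in this library (22.6 CPM against 6.37 to 11.9 CPM in the others, but a log2 difference of 0.12 in the pair numbered 3 after TMM scaling), far below the 1964 CPM of miR-146a-5p. Reads of miR-146b-5p counted as miR-146a-5p are argued against as well, since the ratio of miR-146a-5p to miR-146b-5p was 27.6 times that of control library 3. With 1 library, a difference of that culture or animal may remain and was not tested.

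For the comparison of all 6 libraries the real count of calls is 0, so all 10 of 10 splits into 3 and 3 reach it by construction (highest other 0) and the count of splits decides nothing. For lists, 2 of 10 splits, the real one included, gave at least the real 7. The other of these was control libraries 1 and 3 with CIH library 1, at 12 lists. That split parts 1 pair of equal number; among the 4 splits that part all 3 pairs, the other 3 gave 3 to 6 lists. With 10 splits no share under 0.05 is possible.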
